A study of Rattus norvegicus with 28 samples.

How the data were processed

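Polyadenylated RNA from the nucleus accumbens (NAc) and the medial prefrontal cortex (mPFC) of male Sprague-Dawley rats was sequenced in 28 libraries, 7 for each combination of region and virus. Per the labels, RNA was extracted with Trizol and cleaned on RNeasy Micro columns, and libraries were made with the Illumina TruSeq RNA V2 kit, which does not record strand. Per the submitters' processing notes, the tools named are HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 1.6.3 with genome build rn6; the role of each is not given in the sources used here. The deposited values are raw counts of reads per Ensembl gene, with 1 column per library and no normalization. The deposited table holds 15635 genes. Each of them reaches 10 counts in at least 14 libraries, so a filter on low counts had been applied before deposit, although none is described in the labels. Genes absent from the table were not analysed here. The annotation release is not given in the sources used here.

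The groups were read from the sample titles, which give the region, the virus, a replicate number and a mark, P1 or P2, whose meaning the labels do not state. Each NAc group holds 3 P1 and 4 P2 libraries. The mPFC H3.3WT group holds 4 P1 and 3 P2 libraries, and the mPFC H3.3Q5A group 3 P1 and 4 P2. The mark entered each model as an additive term. No label ties a library to a single animal, so p-values measure the spread between these libraries. No library was left out of the main comparisons. No pair of libraries within a group agreed within sampling noise: the smallest chi-square per degree of freedom between libraries of the same group was 7.49.

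Virus effects were tested within each region on its 14 libraries with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and edgeR's filterByExpr filter. The virus by region interaction and the difference between the regions were tested on all 28 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The region comparison also required a log2 fold change of at least 1 in either direction. Fold changes are log2 of H3.3Q5A over H3.3WT, or of NAc over mPFC, with the standard error (SE) taken from the same fit. Levels are library-size scaled counts (CPM, with TMM factors) computed from the deposited counts. Log2 CPM values used a prior count of 2. Library measures were compared with two-sided exact permutation tests over all 3432 divisions of 14 libraries into equal groups, adjusted over 20 tests.

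Genes are given by Ensembl ID. The reference gene table at hand (assembly GRCr8) pairs no Ensembl ID with a symbol: 0 of the IDs matched. The gene lists, cell type markers and H3.3 genes chosen before the data were examined are written as symbols, so they are not analysed here, and neither are the added transgenes. The rule set before the data were examined named, for each virus comparison, the H3.3 genes, the 15 largest rises and falls among called genes with a symbol and a mean of at least 1 CPM (the 5 smallest p-values each way if fewer than 5 were called), and members of the lists. For the interaction it named the 10 smallest p-values. For the regions it named the 10 largest folds each way at 10 CPM or more and the neuron lists. Without symbols, the rule was applied to IDs and limited to 2 each way per comparison. Other genes that are named were chosen after their values were seen.

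Gene groups were made from the counts instead, after the data were examined. The difference between NAc and mPFC was fitted over both viruses, and genes past an adjusted p of 0.05 with a log2 fold change of at least 2 formed a group of 258 NAc-high and a group of 273 mPFC-high genes. The contrast gave both viruses equal weight, although the filter and the fit had a group for each combination of region and virus. The groups were tested in each virus comparison with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over 6 tests. The estimated correlations were 0.151 to 0.413. The preset p-values therefore treat the genes as more independent than they were. A camera p-value given without naming a correlation used the preset one, as did all camera values under alternative settings. The region score of a library is its mean log2 CPM over NAc-high genes minus that over mPFC-high genes.

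The procedure was tested on simulated data with 200 seeded genes per run, drawn from the means, spreads and library sizes of each region. The seeded genes were spread evenly over the folds given below. Recovery at an adjusted p depends on how many genes change, and fewer changed genes were not simulated. Each gene was drawn independently, so variation that genes share within a library was absent and its part in false calls was not measured. In the NAc simulation, on 15315 genes, edgeR recovered 9.6% of genes changed 1.25-fold, 54.8% at 1.5-fold, 88.4% at 2-fold and 98% at 4-fold, with 4.2 false calls per run. In the mPFC simulation, on 15485 genes, it recovered 21.2%, 62.4%, 84.8% and 97.2% at the same folds, with 7.8 false calls per run. DESeq2 1.42.0, in 2 runs per region, made 26.5 false calls per run in the NAc simulation and 39 in the mPFC simulation. It recovered 67% and 73% of genes changed 1.5-fold. Alternatives planned before the data were examined were DESeq2, limma voom with sample quality weights, median-ratio factors, other filters, no P term, each P mark alone, 2 surrogate variables (sva 3.50.0), one fit over 28 libraries, an adjusted p under 0.10, and leaving out each library. Alternatives with the region score as a term, without the libraries that stood apart, and DESeq2 without the P term were added after seeing the data.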

Results

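Gene expression was measured in the NAc, a part of the ventral striatum that takes part in reward and drug seeking, and in the mPFC, a cortical region that projects to it. Rats had self-administered cocaine under extended access for 10 days. A lentivirus carrying the histone variant H3.3 was then injected into one of these regions, either as the wild-type protein (H3.3WT) or as H3.3Q5A, in which the glutamine that can be modified by dopamine is replaced by alanine. After 30 days of viral expression and abstinence the animals were tested for cocaine-cue seeking. The comparisons ask whether the transcriptome differs between H3.3Q5A and H3.3WT in each region. They also ask whether the effect differs between regions, the contrast named in the title of the study. The level of the modification was not measured in these libraries. Each group held 7 libraries, named here by the replicate number in their titles. The total count averaged 26.7 ± 5.93 M (megacounts, SD, n = 7) in NAc H3.3WT, 26.6 ± 11.5 M in NAc H3.3Q5A, 29.1 ± 7.36 M in mPFC H3.3WT and 36.6 ± 6.72 M in mPFC H3.3Q5A. The smallest library held 15.4 M counts and the largest 51.7 M.

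The comparison of the regions described how the labelled regions differ. It could not check which tissue each label stands for, because no ID was paired with a symbol. Among libraries with H3.3WT, 871 genes were higher in NAc and 1008 were higher in mPFC, of 15635 tested (edgeR quasi-likelihood test, adjusted p under 0.05 and a log2 fold change of at least 1). ENSRNOG00000057031 was at 25.9 ± 3.19 CPM (SD, n = 7) in NAc H3.3WT and at 0.103 ± 0.251 CPM in mPFC H3.3WT, where 5 of the 7 libraries had no count. ENSRNOG00000017712 was at 102 ± 37.7 CPM in NAc and 0.956 ± 1.66 CPM in mPFC. ENSRNOG00000016999 was at 48.6 ± 11.4 CPM in mPFC and 1.63 ± 1.09 CPM in NAc. ENSRNOG00000021256 was at 63.9 ± 16.6 CPM in mPFC and 6.06 ± 6.63 CPM in NAc. The fitted log2 fold changes of NAc over mPFC were 7.96 (SE 0.83), 6.65 (SE 0.93), −4.91 (SE 0.33) and −3.44 (SE 0.47), with edgeR adjusted p-values of 1.1e-08, 1.42e-06, 5.2e-12 and 1.12e-06.

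The mPFC-high genes, taken over both viruses, averaged 3.24 ± 0.16 log2 CPM (SD, n = 7) in mPFC H3.3WT and 0.78 ± 0.53 in NAc H3.3WT. The NAc-high genes averaged 3.80 ± 0.17 log2 CPM in NAc H3.3WT and 0.88 ± 0.18 in mPFC H3.3WT. mPFC H3.3Q5A replicate 34 stood apart, with NAc-high genes at 1.82 log2 CPM where the group averaged 0.96 ± 0.39. Its mPFC-high genes were at 2.85 log2 CPM where the group averaged 3.23 ± 0.19.

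**Figure D1:**
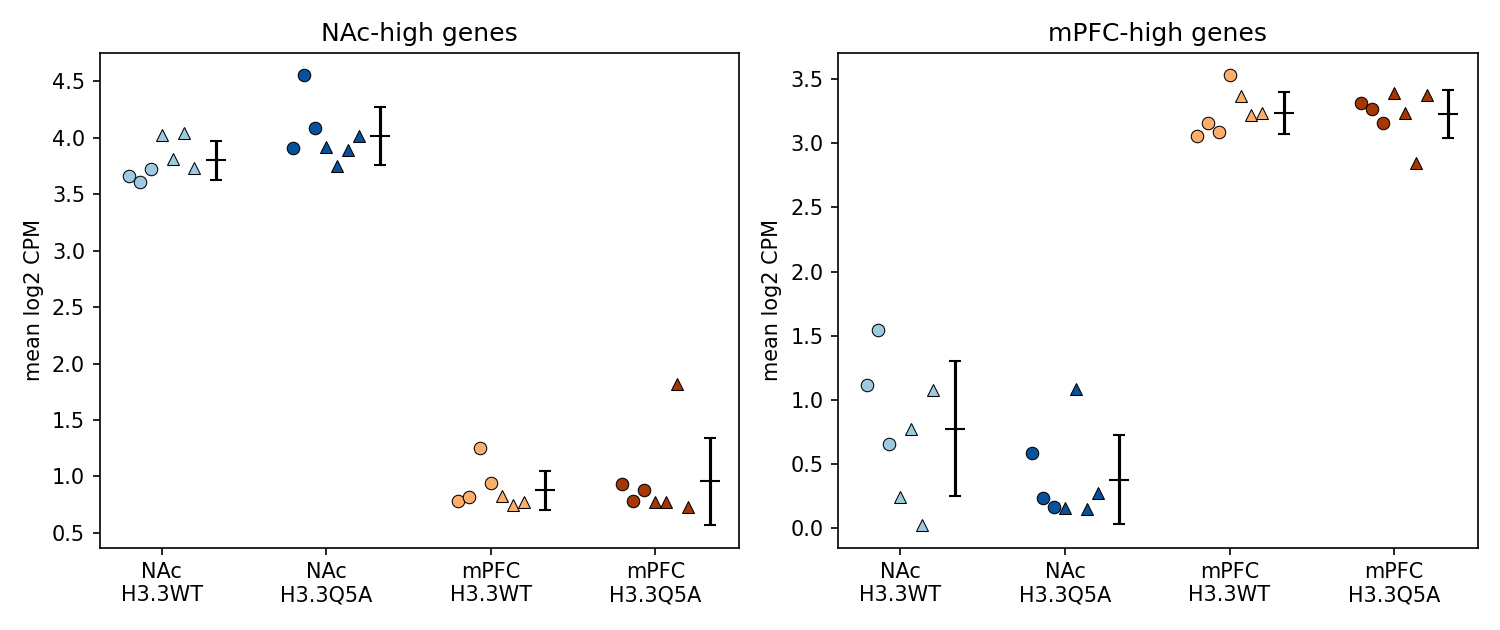
Mean log2 CPM of the 258 NAc-high genes (left) and the 273 mPFC-high genes (right) in each of the 28 libraries, by group. Circles are P1 libraries and triangles P2 libraries, and bars give the mean and SD of the 7 libraries. NAc libraries ranged from 0.02 to 1.54 in mPFC-high genes, and mPFC H3.3Q5A replicate 34 is the mPFC library highest in NAc-high genes, at 1.82.

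In NAc, most genes typical of mPFC had lower levels with H3.3Q5A than with H3.3WT, and most genes typical of NAc had higher levels. The libraries of each group varied widely in these genes. The median log2 fold change of the 197 mPFC-high genes tested was −0.43, with 25 of them above 0. Camera gave an adjusted p of 5.17e-20 with the preset correlation of 0.01 and an adjusted p = 0.204 with the estimated correlation of 0.413. The NAc-high genes had a median log2 fold change of 0.21, with 217 of 258 above 0. For them camera gave an adjusted p of 8.32e-13 with the preset correlation and an adjusted p = 0.204 with the estimated correlation of 0.206. Counted by library, the mPFC-high genes averaged 0.78 ± 0.53 log2 CPM (SD, n = 7) with H3.3WT and 0.38 ± 0.35 with H3.3Q5A, a difference of −0.40 (exact permutation test, p = 0.126, adjusted p = 0.36). The region score was 3.02 ± 0.69 with H3.3WT and 3.64 ± 0.52 with H3.3Q5A (difference 0.61, exact permutation p = 0.0862, adjusted p = 0.342). This difference was 1.30 among P1 libraries (exact p = 0.1, the smallest that 3 against 3 allows) and 0.10 among P2 libraries (exact p = 0.971). The median of the NAc-high genes was 0.11 without NAc H3.3Q5A replicate 3, 0.46 among P1 libraries alone and 0.02 among P2 libraries alone. The median of the mPFC-high genes was −0.88 among P1 libraries alone and −0.15 among P2 libraries alone.

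No single gene passed the edgeR test for the virus in NAc. Of 15315 genes tested, 0 had an adjusted p under 0.05 and 1200 had an unadjusted p under 0.05, 539 higher and 661 lower with H3.3Q5A, where 766 would fall below that limit by chance. DESeq2 called 9 genes, 4 higher and 5 lower, and limma voom with sample quality weights called 4. The smallest edgeR adjusted p was 0.637. Among the genes with the smallest p-values, ENSRNOG00000012031 was at 1.90 ± 0.236 CPM (SD, n = 7) with H3.3WT and 3.003 ± 0.522 CPM with H3.3Q5A, a log2 fold change of 0.66 (SE 0.13). ENSRNOG00000052051 was at 21.98 ± 1.65 and 27.0 ± 2.15 CPM, a log2 fold change of 0.30 (SE 0.07). ENSRNOG00000006789 was at 25.1 ± 2.56 and 19.2 ± 0.886 CPM, a log2 fold change of −0.39 (SE 0.07). ENSRNOG00000019961 was at 93.5 ± 6.68 and 73.0 ± 8.57 CPM, a log2 fold change of −0.36 (SE 0.07). In mPFC H3.3WT the 4 genes averaged, in the same order, 1.68, 3.08, 23.7 and 156 CPM, and ENSRNOG00000052051 is one of the NAc-high genes. For each of the 4 genes, all 7 H3.3Q5A libraries lay on the same side of the H3.3WT mean. The genes were chosen by p-value in these same libraries, so this adds no support. DESeq2 called these 4 genes, at adjusted p-values from 0.00158 to 0.0393, but lost ENSRNOG00000012031 without any 1 of 8 libraries and ENSRNOG00000052051 without any 1 of 10. The edgeR log2 fold changes of these 2 genes stayed at 0.591 to 0.712 and 0.264 to 0.328 with each library left out. DESeq2 called between 2 and 406 genes when single libraries were left out. The count at an unadjusted p under 0.05 was 713 without NAc H3.3Q5A replicate 7 and 2128 without NAc H3.3WT replicate 21, and edgeR called 1 gene without NAc H3.3WT replicate 12.

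The median SE of a gene's log2 fold change in NAc was 0.118. The 95% confidence interval lay within a 1.5-fold change either way for 77.4% of genes and within a log2 change of 1 for 94.6%.

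In mPFC, the medians of the same gene groups depended on which libraries were used. The median log2 fold change of the 273 mPFC-high genes was −0.02, with 127 above 0 (camera adjusted p = 0.116), and it was 0.03 among P1 libraries alone (camera unadjusted p = 0.049) and −0.06 among P2 libraries alone (camera unadjusted p = 0.00109). The camera unadjusted p was also under 0.05 without mPFC H3.3WT replicate 3 or 11 or mPFC H3.3Q5A replicate 4 or 37. The 194 NAc-high genes tested had a median of 0.14, with 137 above 0 (camera adjusted p = 0.0176, and adjusted p = 0.648 with an estimated correlation). That median was −0.04 without mPFC H3.3Q5A replicate 34, −0.06 among P1 libraries alone and 0.30 among P2 libraries alone, and the camera unadjusted p was over 0.05 without mPFC H3.3WT replicate 13, 21 or 35 or mPFC H3.3Q5A replicate 34. The region score was −2.36 ± 0.25 (SD, n = 7) with H3.3WT and −2.27 ± 0.56 with H3.3Q5A (exact permutation p = 0.821, adjusted p = 0.981).

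No single gene passed the edgeR test in mPFC either. Of 15485 genes tested, 0 had an adjusted p under 0.05 and 1221 had an unadjusted p under 0.05, 661 higher and 560 lower with H3.3Q5A, where 774 would be reached by chance. DESeq2 called 8 genes, 3 higher and 5 lower, and limma voom with sample quality weights called 0. The smallest edgeR adjusted p was 0.626. ENSRNOG00000000121 was at 11.3 ± 0.926 CPM (SD, n = 7) with H3.3WT and 14.1 ± 0.706 CPM with H3.3Q5A, a log2 fold change of 0.34 (SE 0.07). ENSRNOG00000027630 was at 20.7 ± 3.17 and 29.6 ± 3.38 CPM, a log2 fold change of 0.52 (SE 0.11). ENSRNOG00000021410 was at 117 ± 17.02 and 85.7 ± 12.4 CPM, a log2 fold change of −0.42 (SE 0.09). ENSRNOG00000005781 was at 3.88 ± 0.546 and 2.33 ± 0.564 CPM, a log2 fold change of −0.71 (SE 0.15). All 7 H3.3Q5A libraries lay on the same side of the H3.3WT mean for each of these 4 genes, which choosing them by p-value in these libraries favours. DESeq2 called these 4 genes at adjusted p-values from 0.0233 to 0.0393. Each of these calls ended without any 1 of 8 to 11 libraries. With each library left out, the edgeR log2 fold changes were 0.313 to 0.370 and 0.443 to 0.578 for the genes higher with H3.3Q5A. For the lower ones they were −0.481 to −0.369 and −0.794 to −0.626. DESeq2 called between 0 and 39 genes when single libraries were left out. Without the P term it did not call ENSRNOG00000021410 (DESeq2 adjusted p = 0.0796). The median SE was 0.0999, and the 95% confidence interval lay within a 1.5-fold change for 79.3% of genes. The count at an unadjusted p under 0.05 was 705 without mPFC H3.3WT replicate 36, 2020 without mPFC H3.3WT replicate 13 and 398 among P1 libraries alone.

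**Figure D2:**
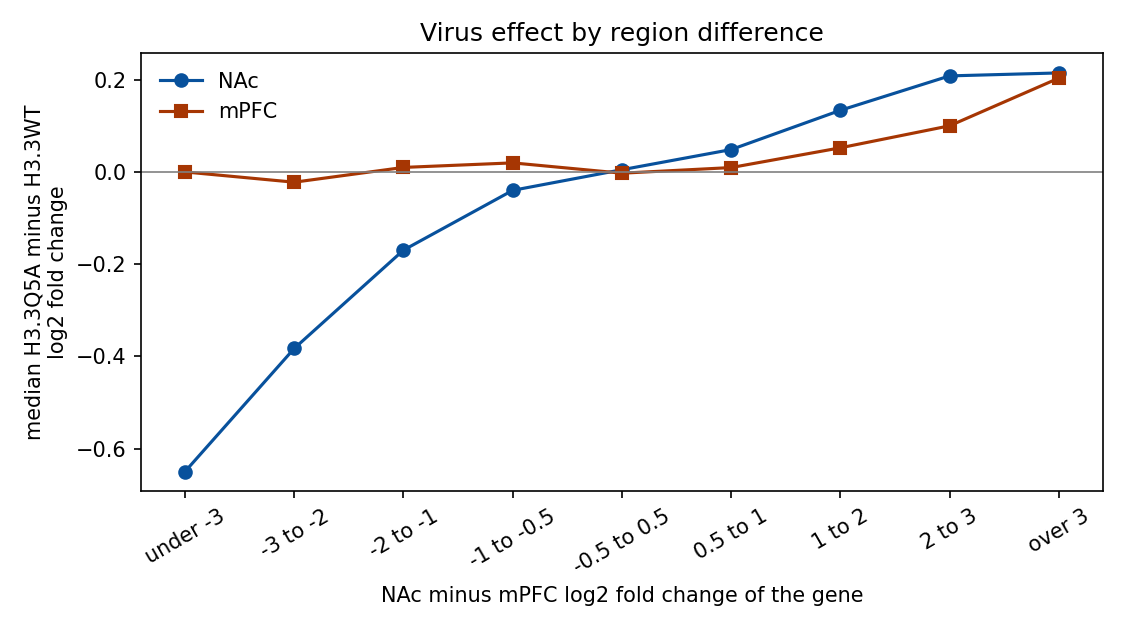
Median log2 fold change of H3.3Q5A over H3.3WT (vertical axis) for genes binned by their log2 fold change of NAc over mPFC (horizontal axis), in NAc (circles) and in mPFC (squares). In NAc the median ran from −0.65 for the 40 genes tested there that are most typical of mPFC to 0.21 for the 102 most typical of NAc, and in mPFC it ran from 0.00 (68 genes tested) to 0.20 (63 genes tested). Without mPFC H3.3Q5A replicate 34, the mPFC median of all NAc-high genes was −0.04.

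The effect of the virus was compared between regions directly. The mPFC-high genes had a median interaction (NAc effect minus mPFC effect) of −0.44 on the log2 scale, with 50 of 273 above 0. Camera gave an adjusted p of 2.66e-15 with the preset correlation and an adjusted p = 0.204 with an estimated correlation. The NAc-high genes had a median interaction of 0.084, with 156 of 258 above 0 (camera adjusted p = 0.0064, and adjusted p = 0.648 with an estimated correlation). No single gene passed the edgeR interaction test: 0 of 15635 had an adjusted p under 0.05, and 813 had an unadjusted p under 0.05, where 782 would be reached by chance. The latter count was 1258 without NAc H3.3WT replicate 21, 1325 without the 2 libraries of lowest median correlation in each region and 1806 with voom. DESeq2 also called 0 genes and limma voom with sample quality weights called 5. ENSRNOG00000014371 had an interaction of 0.34 (SE 0.08), ENSRNOG00000021410 of 0.61 (SE 0.15), ENSRNOG00000018755 of −0.37 (SE 0.09) and ENSRNOG00000006789 of −0.41 (SE 0.10), each at an edgeR adjusted p of 0.909. ENSRNOG00000021410, at 117 and 85.7 CPM in mPFC as given above, was at 99.96 ± 20.01 CPM (SD, n = 7) with H3.3WT and 113 ± 7.52 CPM with H3.3Q5A in NAc.

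The regions came from different libraries, so their virus effects could be set side by side without shared controls. Across 15173 genes, which are not independent replicates, the log2 fold changes in NAc and mPFC had a Spearman correlation of 0.168 and a Pearson correlation of 0.145, and 57.7% had the same sign. At an unadjusted p under 0.05 in both regions, 44 genes were higher and 57 lower with H3.3Q5A in both, where independent lists would share 22.8 and 23.9. Another 13 went in opposite directions, where independent lists would give 47.6; this number was 8, 20 and 24 without NAc H3.3WT replicates 8, 17 and 21, 8 without NAc H3.3Q5A replicate 7, 18 or 28, and 24, 25 and 7 without mPFC H3.3WT replicates 13, 21 and 36. The Spearman correlation was 0.109 among P1 libraries and −0.14 among P2 libraries. On leaving out each library it ranged from 0.0951 without mPFC H3.3Q5A replicate 34 to 0.242 without NAc H3.3WT replicate 17. The number of genes in the same direction, 101, was 54 without NAc H3.3Q5A replicate 7, 62, 65 and 198 without NAc H3.3WT replicates 8, 23 and 21, 60, 155 and 57 without mPFC H3.3WT replicates 3, 13 and 36, and 56, 63 and 62 without mPFC H3.3Q5A replicates 2, 34 and 37.

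The P mark was also examined by itself. edgeR called 0 genes between P1 and P2 in NAc, with 681 at an unadjusted p under 0.05, and 0 in mPFC, with 953. DESeq2 called 1 gene in NAc and 37 in mPFC.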

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

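The tests of the depth difference, of genes alike in both regions, of the count of genes in the same direction, of the region score as a term and of the NAc share in mPFC libraries were chosen only after the results they bear on had been seen.

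The response to the virus of genes that distinguish the regions was compared between regions. The median interaction of the mPFC-high genes was −0.44 on the log2 scale and that of the NAc-high genes was 0.084, both past the camera test with the preset correlation and neither with an estimated one. With virus labels redrawn within region and P mark, 12 of 100 splits gave a median as far from 0 for the mPFC-high genes (highest other −0.70) and 82 of 100 for the NAc-high genes (highest other 0.54), so chance could not be excluded for either. In NAc alone, 16 of 100 splits gave a median as far from 0 as −0.43 for the mPFC-high genes (highest other −0.76) and 11 of 100 as far as 0.21 for the NAc-high genes (highest other 0.33). In mPFC, the corresponding numbers were 80 of 100 for −0.02 (highest other 0.18) and 68 of 100 for 0.14 (highest other −0.30), so chance could not be excluded in these 4 cases either.

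A candidate explanation for the NAc pattern is an unequal share of cortical tissue in the dissected NAc samples. It predicts that genes with a larger mPFC excess are lower with H3.3Q5A by more, and within the 197 mPFC-high genes the NAc virus fold change had a Spearman correlation of 0.415 with the NAc over mPFC fold change, across genes. A response of region-specific genes to H3.3Q5A in NAc stays open and was not tested apart from the share of tissue, since the same genes would measure both. Chance remains open as well, as the splits show.

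The virus effects in NAc and mPFC pointed in the same direction more often than in opposite ones, but of 100 splits 18 gave a Spearman correlation as high as 0.168 (highest other 0.416), so chance could not be excluded for the correlation. The 101 genes in the same direction were matched by 2 of 100 splits, the real one included (highest other 376). Few splits thus reached this count, but it also rises with the number of genes at an unadjusted p under 0.05. In the split that gave 376, these were 2810 in NAc and 2095 in mPFC, against 1200 and 1221 in the real one. The count was also singled out after the splits had been seen, as 1 of 4 measures of agreement. Chance therefore stays open for it. The tables argue against depth, since the H3.3Q5A minus H3.3WT difference in total count was −0.132 M in NAc and 7.47 M in mPFC. The correlation was 0.157 over the 13508 genes kept when the 1665 differing between regions by a log2 fold change of 1 or more were left out. It therefore did not rest on those 1665 genes. Smaller differences stayed in, since 8340 genes differed between regions at any fold (edgeR adjusted p under 0.05). Unequal shares of the other region's tissue stay open because 2 tests point opposite ways: the correlation was 0.185 over the 6786 genes differing by under 0.25, but −0.0491 with the region score as a term, which gave 21 genes in the same direction in place of 101, and a shared response to the virus stays open as well.

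A pair of mPFC libraries carried more NAc-high transcripts than the others. The NAc-high level was 1.82 log2 CPM in mPFC H3.3Q5A replicate 34 (next highest 0.94) and 1.248 in mPFC H3.3WT replicate 11 (next highest 0.94), the mPFC-high level of replicate 34 was 2.85, and the region scores were −1.03 and −1.84. ENSRNOG00000057031 was at 0.671 CPM and ENSRNOG00000017712 at 4.66 CPM in replicate 11, each above the other H3.3WT libraries of mPFC. Replicate 34 held them at 2.41 and 19.2 CPM, each above the other H3.3Q5A libraries of mPFC. NAc tissue mixed into these samples may account for this, and the excess of each NAc-high gene over the other mPFC libraries would then be one share of its NAc level. In replicate 34 that share had a median of 10.2%, but its upper quartile was 5.45 times its lower one (95% bootstrap interval 3.31 to 8.05), and 219 of 258 genes lay above 0. That ratio was past the limit written for this test as counting against one common share, but the lower end of the interval was not. The written limit did not use the interval. In replicate 11 the share had a median of 2.90% (quartiles −0.309% and 6.20%), with 186 of 258 genes above 0. Mixed-in NAc tissue stays open because of the spread between genes in single libraries. Tissue from a region near the NAc stays open as well, and no biological explanation was tested.

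Other libraries lay far from the rest of their group. NAc H3.3Q5A replicate 22 held 51.7 M counts. The 10 most abundant genes took 4.14% of the counts in NAc H3.3Q5A replicate 3 and 3.08% in mPFC H3.3Q5A replicate 34. The median correlation with the other libraries of the region was 0.965 in NAc H3.3WT replicate 17, 0.973 in NAc H3.3Q5A replicate 3 and 0.974 in mPFC H3.3WT replicate 13. NAc H3.3Q5A replicate 3 had an NAc-high level of 4.55 log2 CPM and ENSRNOG00000014371 at 240.0 CPM. ENSRNOG00000021410 was at 56.6 CPM in NAc H3.3WT replicate 17. ENSRNOG00000021256 was at 20.2 CPM in NAc H3.3WT replicate 12. In all, 17 values were this far out in 60 groups of 7 values tested, where chance gives about 3, and several come from the same library.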

How the results depend on the processing

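Of 383 alternative values of the 16 named gene results, 363 kept direction and side of the threshold, 20 passed it and none reversed. These genes were chosen by p-value or fold in these libraries, so this adds no support. The count of NAc vs mPFC genes ranged from 1879 to 2135. edgeR's 0 calls for the virus became 9 in NAc and 8 in mPFC with DESeq2, 8 and 7 with DESeq2 without the P term, and 4 in NAc and 5 for the interaction with limma voom and quality weights. Without the 2 libraries of lowest median correlation in each region the interaction gave 1. Leaving out each library gave 0 to 1 genes in NAc and 0 in mPFC and for the interaction. The count at an unadjusted p under 0.05 in NAc, 1200, was 372 among P2 libraries, 599 with the region score as a term, 2435 with 2 surrogate variables and 2971 with voom. The count of genes in the same direction in both regions, 101, was 165 with DESeq2, 208 with DESeq2 without the P term, 271 with voom, 182 with 2 surrogate variables, 28 among P1 libraries, 8 among P2 libraries and 21 with the region score as a term; leaving out each library gave 54 to 198. The 13 genes in opposite directions were 79 with voom, 48 with 2 surrogate variables, 51 without the 2 libraries of lowest median correlation, 22 among P1 libraries and 8 with all libraries in one fit; leaving out each library gave 7 to 25. The correlation of virus effects was −0.139 among P2 libraries and −0.0491 with the region score as a term, and 0.0951 to 0.242 on leaving out each library. The median of the mPFC-high genes turned to 0.00407 in NAc with the region score as a term, which is computed from the same genes. In mPFC it turned to 0.0251 among P1 libraries, 0.0547 without the 2 libraries of lowest median correlation, 0.0114 with the region score and 0.00209 without the 2 libraries richest in NAc-high genes, and ranged from −0.0526 to 0.024 on leaving out each library. The NAc-high median in mPFC turned to −0.0632 among P1 libraries and −0.0356 without the 2 libraries of lowest median correlation, and ranged from −0.0413 to 0.186 on leaving out each library. The NAc-high genes missed camera's unadjusted limit of 0.05 in NAc among P2 libraries (median 0.0201) and with the region score (0.0303). In mPFC they missed it with no filter (median 0.139), with the region score (0.0377) and without the 2 libraries richest in NAc-high genes (0.0262). The same held in mPFC where the sign turned and without any 1 of 3 libraries. Settings with P1 or P2 alone, or fewer libraries, test fewer libraries; otherwise the cause was not tested. The alternatives listed earlier as added, and all of the agreement between regions and the region gene groups, were chosen after seeing the data.

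The tests of the gene lists, with their alternatives, and the fits with an oligodendrocyte term were not run, because no ID was paired with a symbol. For ENSRNOG00000017712, DESeq2 gave no adjusted p in the region comparison. No paired analysis was possible because the groups share at most 1 replicate number. A 95% confidence interval within a log2 change of 1 was found for 71.6% of NAc and 73.5% of mPFC genes under 1 CPM, and for 98.3% and 98.6% of those over 10 CPM.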

Other observations

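The tests of chance below were planned before their results were seen; the reading of the single-library test was changed afterwards, as said. For the genes at an unadjusted p under 0.05, chance could not be excluded. In NAc, 15 of 100 splits gave as many genes as the real one (real 1200, highest other 2810), in mPFC 17 of 100 (real 1221, highest other 2648), and for the interaction 41 of 100 (real 813, highest other 2097). For the regions, 1 of 100 splits, the real one, gave as many as 1879 genes (highest other 332), so chance was excluded.

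DESeq2's calls were set against 100 splits, of which 50 had been run and read before the rest (6 of 50 as many in NAc and 5 of 50 in mPFC). In NAc 10 of 100 splits gave 9 or more genes (highest other 1002), and in mPFC 13 of 100 gave 8 or more (highest other 288), so chance could not be excluded for either. Splits with far more calls than the real one point to a structure among the libraries. When each library was left out in turn, 7 of the 9 NAc genes and 8 of the 8 mPFC genes lost the DESeq2 call for some library. The limit set beforehand would count this as dependence on single libraries. In NAc, leaving out H3.3Q5A replicate 7 ended all 7 of these calls, and leaving out H3.3WT replicate 8 or H3.3Q5A replicate 18 ended 6 each. In mPFC each of 5 libraries ended all 8. A median of 4 libraries in NAc and 10.5 in mPFC ended a gene's call. In mPFC each of the 8 calls ended without any 1 of 8 to 12 libraries. Calls that so many different libraries could end do not point to a single one, and the DESeq2 adjusted p-values were 0.0233 to 0.0498, near the limit. Since the limit set beforehand was met, dependence on single libraries stays open in both regions. ENSRNOG00000006789 and ENSRNOG00000019961 in NAc lost the call for no library. The number of DESeq2 calls in NAc ranged from 2 without H3.3Q5A replicate 7 to 406 without H3.3WT replicate 21, and was 51, 17, 15 and 4 without H3.3Q5A replicates 19, 2, 22 and 18 and 36, 5, 5 and 4 without H3.3WT replicates 17, 14, 20 and 8. In mPFC it ranged from 0 without H3.3WT replicates 6, 35 and 36 or H3.3Q5A replicate 2 to 39 without H3.3WT replicate 13. It was 1, 3 and 2 without H3.3WT replicates 3, 11 and 21, and 17, 20, 1, 2 and 3 without H3.3Q5A replicates 4, 14, 15, 34 and 37.

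Replicates 21 and 19 lay at the other group's end of the region score in NAc. H3.3WT replicate 21 had a score of 4.02, where its group averaged 3.02 ± 0.69 (SD, n = 7), and H3.3Q5A replicate 19 had 2.66, where its group averaged 3.64 ± 0.52. Over the 46 NAc-high genes with a log2 fold change of at least 4 between regions, the share of the NAc level above the other mPFC libraries had a median of 8.28% in mPFC H3.3Q5A replicate 34 and 2.74% in mPFC H3.3WT replicate 11, and from −0.53% to 0.31% in the other 12 mPFC libraries.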
